A study of Mus musculus with 6 samples.

How the data were processed

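RNA-seq was analysed in 6 mouse lymphocyte libraries, 3 titled as carrying floxed Rora alleles and 3 titled treatment. The series text compares wild-type with conditional knockout (cKO) ILC1s, group 1 innate lymphoid cells, so the treatment libraries were taken as the cKO group by elimination. The columns of these libraries add the name Ncr1 to Rora, and those of the floxed libraries do not. The labels give no sort gate and no number of animals. They do not say whether the replicates of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted with TRIzol and 2 µg entered a stranded mRNA library kit.

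STAR 2.5.3a, featureCounts, Subread 1.5.1, edgeR 3.12.1 and the build mm10 were used, per the submitters' processing notes. The role of each tool, the strand setting of the counting, the handling of duplicate reads and the annotation version are not given in the sources used here. The deposited table holds RPKM, reads scaled to gene length and library depth, for 24628 genes in each library, together with exon coordinates and a gene length in bases. Symbols were used as the authors wrote them; 21 of them are spreadsheet dates and were not named. All 6 columns of expression values were mapped to samples. Of the tested genes, 12336 matched GENCODE M21 by symbol, which served only for gene types; coordinates are those of the deposited table.

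RPKM multiplied by gene length fell on whole multiples of a fixed step in each library for 100% of values, within 0.001 reads. The recovered depth was 20152146 to 22440170 reads per library, and summed reads of gene families are given as RPM, scaled to this depth. At this depth Rora rested on 1668 to 2237 reads per library, and the microRNA gene Mir3058 on 0 to 2 in floxed and 10 to 17 in cKO libraries. Pairs of libraries were compared by chi-square on recovered reads. At 20 to 100 summed reads per gene the statistic per gene was 4.94 to 5.46 within groups, about 5 times counting noise, and at 500 or more summed reads it was 6.79 to 15.8 within and 19.9 to 28.6 between groups. No pair differed by as little as sampling noise, and at 20 to 100 summed reads pairs between groups were at 5.32 to 5.96. The handling of duplicate reads is not given, so this excess does not show that the libraries are separate samples. Each library was counted as 1 replicate.

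The main test, fixed before the data were examined together with the gene lists, the rule for named genes and most alternatives, was limma 3.58.1 in R 4.3.3. It used lmFit and eBayes with a mean-variance trend on log2(RPKM + 1), without further scaling or covariates, on all 6 libraries. Genes with at least 1 RPKM in at least 3 of the 6 libraries entered, which left 12731. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are cKO minus floxed on the log2(RPKM + 1) scale, which understates the change of low genes. Levels are mean RPKM ± SD over the 3 libraries of a group. For Rora an exact permutation test of the group means was added, two-sided over 20 assignments, whose smallest possible p is 0.1.

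Gene lists were tested with camera of limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 of 33 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. For each list the passing members were also counted after adjustment over the list alone. The lists covered type 1 ILC and NK identity, ILC1 and conventional NK markers, cytotoxic effectors, cytokines, cytokine receptor signalling, memory and homing, trafficking, checkpoint receptors, S phase, mitosis, apoptosis, cholesterol synthesis, the circadian clock, glycolysis, oxidative phosphorylation, fatty acid oxidation, ribosome biogenesis, interferon-stimulated genes, immediate-early and dissociation-response genes, mitochondrially encoded genes and ribosomal proteins. Further lists held markers of ILC2s, ILC3s, B cells, plasma cells, T cells, macrophages, dendritic cells, neutrophils, erythroid, stromal and liver cells. Symbol families with at least 5 tested members were tested for an excess of passing genes by Fisher's exact test, adjusted over 328 families, a step chosen after the gene calls were seen. This test takes genes as independent, although genes of a family can vary together, so its p does not measure the spread between libraries.

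The text names Rora, then the 12 passing genes with the largest increase and the 12 with the largest decrease whose groups did not overlap and whose mean was at least 1 RPKM. Predicted genes, clone names, pseudogenes and antigen receptor segments were left out of that ranking, which removed 11 higher and 19 lower genes. In each list at most 4 passing members by smallest p and 2 others by expression may be named, and 9 genes that define the cells are given whether or not they passed. Slfn1, Slfn2, Slfn5 and Klf6 were chosen after their values were seen. The values of 1 list member are not reported here.

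The processing limits some values. Reads of near-identical genes, such as Hspa1a and Hspa1b or the Klra family, can be split between copies, and since the strand setting is not given, a gene and its antisense partner cannot be told apart. In the table, 258 tested genes lie wholly inside same-strand exons of another gene. RPKM over a whole gene keeps exons outside a deleted part.

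Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 RPKM, libraries centred on their median ratio, quantile normalization, limma without the trend, sample quality weights, an absolute log2 difference of at least 1, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were limma voom on the recovered reads and fits without genes on X and Y, without genes shorter than 200 bases, and without genes that share exon bases with another gene. The fits were tested on simulated reads for this comparison, with 200 of 12650 genes changed. Of the genes changed 1.5-fold, 34% were recovered, and of those changed 2-fold, 66%; 7 of 107 calls were not changed genes. With no gene changed, limma made 0 calls, with 607 genes at an unadjusted p under 0.05. A list changed 1.3-fold was called, and 0 of 20 unchanged lists were. Genes were simulated independently and these lists drawn at random, so the run does not cover lists whose members vary together. Tables of exon overlap and plots were made in Python 3.11.15 with matplotlib 3.10.9.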

Results

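Gene expression was measured by RNA-seq in 6 mouse lymphocyte libraries, described in the series text as ILC1s, innate lymphocytes that produce interferon-γ and share many genes with natural killer (NK) cells. The comparison was between 3 libraries with floxed Rora alleles and 3 cKO libraries, Rora being the gene of the nuclear receptor RORα. The floxed libraries held 21711523, 20152146 and 21635232 reads assigned to genes, and the cKO libraries 22440170, 21111333 and 22062140. The 10 most abundant genes took 4.65 to 4.79% of reads in floxed and 4.89 to 5.10% in cKO libraries. The first principal component held 26.5% of the variance and placed the groups apart, with floxed libraries at -17.65 to -11.34 and cKO libraries at 11.76 to 15.75.

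Rora itself (chromosome 9, 68653786 to 69388246, plus strand, mm10) was at 7.42 ± 0.493 RPKM (SD, n = 3) in floxed and 6.07 ± 0.334 RPKM (n = 3) in cKO libraries, or 81.9% of the floxed level. All 3 cKO values lay below all 3 floxed values, and an exact permutation test gave p = 0.1, the smallest that 20 assignments allow. The log2 difference was -0.25 (SE 0.08, 95% confidence interval -0.44 to -0.06), and limma's Benjamini-Hochberg adjusted p = 0.242 did not pass. With limma voom on recovered reads the difference was -0.29 and adjusted p = 0.0242, within a range of 0.0242 to 0.464 over the alternatives run on Rora. The labels do not say which part of Rora is deleted, and whole-gene RPKM keeps exons outside it, so this value does not check the deletion.

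The cKO libraries held more RNA of several immediate-early genes, of the inducible HSP70 genes and of several Ly49 receptor genes, and less RNA of Klrb1b and Il2ra. Among 12731 tested genes, 83 rose and 85 fell in the cKO group. Hspa1b, which encodes inducible HSP70, rose from 34.3 ± 1.16 to 115.8 ± 6.07 RPKM (SD, n = 3 each), and the AP-1 subunit gene Fos rose from 168 ± 0.819 to 346 ± 13.7 RPKM. Klra9, which encodes a Ly49 receptor for MHC class I, rose from 23.1 ± 2.19 to 54.1 ± 4.98 RPKM. Klrb1b, which encodes a receptor of the NKR-P1 family, fell from 167 ± 2.26 to 92.0 ± 2.49 RPKM, and Il2ra, the IL-2 receptor α chain (CD25), fell from 14.5 ± 0.638 to 7.45 ± 0.725 RPKM.

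**Figure D1:**
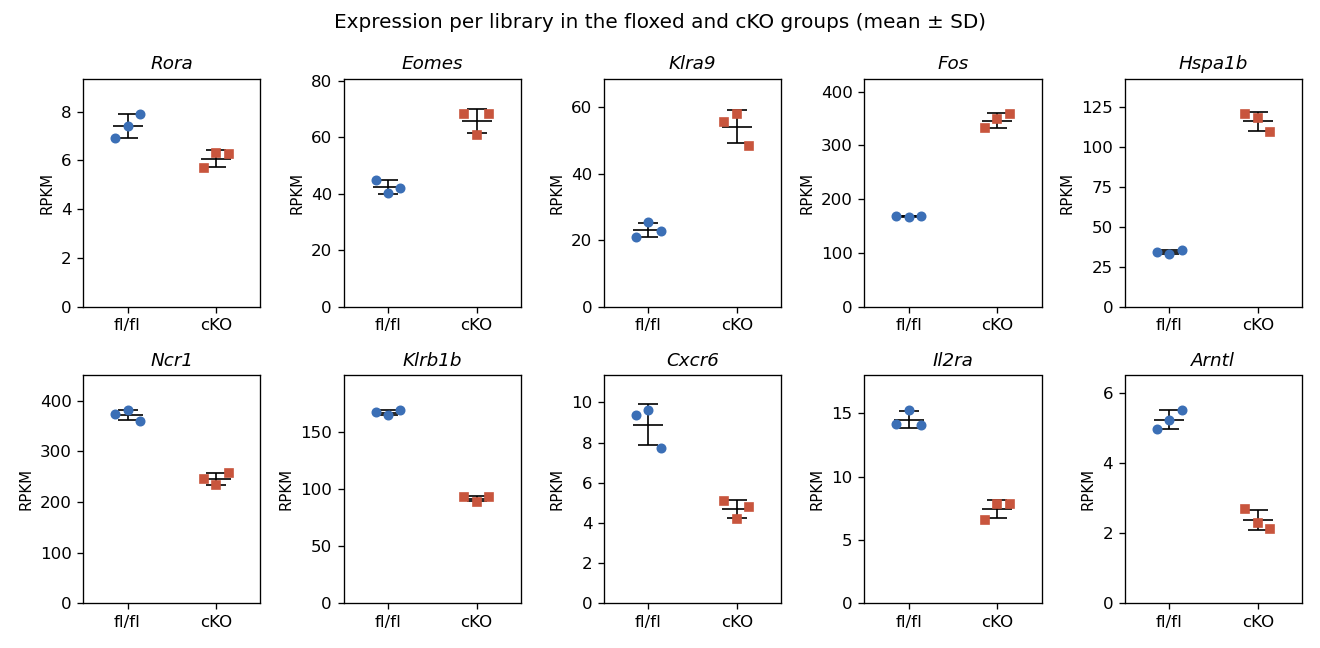
Each panel plots RPKM (vertical axis, from 0) of 1 gene in the 3 floxed (circles) and 3 cKO (squares) libraries, with horizontal bars for the group mean ± SD. Eomes, Klra9, Fos and Hspa1b passed as higher in cKO and Ncr1, Klrb1b, Cxcr6, Il2ra and Arntl as lower, while Rora did not pass although its groups do not overlap.

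The largest increases by the fixed rule were, in log2 difference, those of Mir3058 (2.34), Hspa1a (1.94), Hspa1b (1.73), Mir24-2 (1.48), Mir3074-2 (1.24), Klra9 (1.19), the zinc-finger factor gene Klf4 (1.05), Fos (1.04), the cyclin-dependent kinase inhibitor gene Cdkn1c (0.94), the Y-linked genes Ddx3y (0.93) and Eif2s3y (0.89), and the stress-induced factor gene Atf3 (0.86). The largest decreases were those of Xist (-1.65), the RNA that silences the inactive X chromosome, and its antisense gene Tsix (-1.36), followed by the keratin gene Krt83 (-1.22), Mir7092 (-1.12), Tnfrsf25 (-0.94), which encodes the TL1A receptor DR3, the clock gene Arntl (-0.89), Il2ra (-0.88), Klrb1b (-0.86), the clock gene Cry1 (-0.85), the fatty acid transporter gene Slc27a6 (-0.85), the interferon-induced Rsad2 (-0.85) and the G protein gene Gna15 (-0.83). By the rule, the 3 values of each group lay apart in all 24 genes. Limma's adjusted p ranged from 0.000185 for Hspa1b to 0.0444 for Mir7092. Hspa1b lies on chromosome 17 at 34956436 to 34959238, Klra9 on chromosome 6 at 130178675 to 130193112, Klrb1b on chromosome 6 at 128813706 to 128826331 and Xist on chromosome X at 103460375 to 103483217, in mm10.

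Of all tested genes, 1801 had an unadjusted p under 0.05, and 2583 (20.3%) had groups that did not overlap, against 10% by chance. The called genes included 68 higher and 66 lower protein-coding genes, 12 genes on X or Y, 15 genes shorter than 200 bases and 60 that share exon bases with another gene. Mir3058 rested on 0 to 17 reads per library, Mir7092 on 7 to 21, Mir24-2 on 11 to 48 and Mir3074-2, which lies antisense to Mir24-2 over all of its length, on 11 to 33. Reads of the near-identical Hspa1a and Hspa1b summed to 127.7 ± 5.95 RPM (reads scaled to library depth) in floxed and 453 ± 20.9 RPM in cKO libraries. Leaving out 1 library left 33 to 50 higher and 27 to 39 lower genes, voom on recovered reads called 226 higher and 307 lower, and an absolute log2 difference of at least 1 was reached by 13 higher and 10 lower genes. The calls of Hspa1a, Hspa1b, Klra9, Klf4, Fos, Ddx3y, Eif2s3y, Xist, Tsix, Krt83, Tnfrsf25, Il2ra and Klrb1b held in every refit run on them, the limit on the size of the difference left aside, and each of the other 11 genes lost its call in at least 1. With that limit, Ddx3y, Eif2s3y, Tnfrsf25, Il2ra and Klrb1b also drop out.

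Of 16 markers of ILC1s, 3 passed as lower and 1 as higher in the cKO libraries, and of 16 markers of conventional NK cells, 5 passed as higher, 4 of them Ly49 receptor genes. Cxcr6, the receptor for the chemokine CXCL16, fell from 8.90 ± 1.04 to 4.69 ± 0.453 RPKM (n = 3 each; adjusted p = 0.0241), and the cytokine receptor genes Il18r1 (236 ± 6.04 to 192 ± 3.08 RPKM) and Il7r (228 ± 5.49 to 190.5 ± 1.93 RPKM) fell as well. Eomes, a T-box factor of NK cells, rose from 42.4 ± 2.44 to 65.8 ± 4.31 RPKM (adjusted p = 0.0106). Klra3 rose from 11.5 ± 0.00543 to 18 ± 0.656 RPKM and Klra8, which encodes the activating receptor Ly49H, from 54.1 ± 3.28 to 84.0 ± 3.0 RPKM. Against its list, the early activation marker Cd69 rose from 21.4 ± 1.11 to 32.8 ± 0.437 RPKM.

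The other 12 ILC1 markers did not pass, and adjusted over the list alone 1 rose and 7 fell. The median log2 difference was -0.26 and camera gave adjusted p = 0.00259 (adjusted p = 0.207 with an estimated correlation). Itga1 was at 6.93 ± 0.393 and 5.34 ± 0.503 RPKM (log2 difference -0.33, adjusted p = 0.181) and Zfp683, which encodes Hobit, at 5.12 ± 0.665 and 3.76 ± 0.510 RPKM (-0.36, adjusted p = 0.272). Of the NK markers, 0 fell and 11 did not pass in limma, with 8 above and 0 below at an unadjusted p under 0.05 and 7 and 0 passing with voom. Adjusted over the list alone, 7 rose and 0 fell. Their median was 0.16 and camera gave adjusted p = 7.42e-08 (adjusted p = 0.0667 with an estimated correlation). Itga2, which encodes CD49b, was at 19.5 ± 1.40 and 19.98 ± 0.314 RPKM (adjusted p = 0.867). The median over the 6 Klra members was 0.61 and over the other 10 NK markers 0.06. Among all 11 tested genes with the stem Klra, 7 rose (Fisher's exact test, adjusted p = 8.2e-11). That test takes genes as independent, while these paralogs can share reads, so its p does not measure the spread between libraries. The summed reads of 14 Klra genes were 304.4 to 330 RPM in floxed and 510.2 to 522.5 RPM in cKO libraries. Il18r1 and Il7r lost their calls when any of the 6 libraries was left out, Cxcr6 with any but floxed replicate 3, and Eomes without floxed replicate 3 or cKO replicate 1 or 3. The same cKO libraries had lower Xist (log2 difference -1.65), higher Ddx3y (0.93) and higher immediate-early genes (median 0.46, 16 of 26 rose). They also had lower Cd74, H2-Ab1, Cd22 and Cd3e, and higher Cd247, from B, dendritic and T cell lists that were not called. The other members of these lists did not pass in either direction. The macrophage list lay at a median of -0.15 with 0 of 5 members passing (adjusted p = 0.207 with an estimated correlation).

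Genes shared by ILC1s and NK cells moved in both directions. Ncr1, which encodes NKp46, fell from 372 ± 10.8 to 246 ± 12.5 RPKM (n = 3 each; adjusted p = 0.00446), and Cd226, which encodes DNAM-1, fell from 45.2 ± 2.10 to 29.1 ± 1.97 RPKM. Nfil3, a factor needed for NK cell development, rose from 43.3 ± 1.34 to 56.4 ± 2.36 RPKM. Tbx21, which encodes T-bet, was at 46.7 ± 4.60 and 39.9 ± 0.420 RPKM (adjusted p = 0.256) and Klrb1c, which encodes NK1.1, at 103 ± 5.09 and 99.4 ± 4.01 RPKM (adjusted p = 0.745). Of the 22 shared identity genes, 1 rose, 4 fell and 17 did not pass, against 4 and 10 adjusted over the list alone. Their median was -0.06 and camera gave adjusted p = 0.0466 (adjusted p = 0.207 with an estimated correlation), a call kept in 7 of 21 alternatives. The column names of the cKO libraries contain Ncr1, and whether the Ncr1 locus was modified is not given in the sources used here. Nfil3 lost its call when any of the 6 libraries was left out, and Klrb1b shares 26.9% of its exon bases with the predicted gene Gm44511 on the same strand. The same cKO libraries had lower Xist (log2 difference -1.65), higher Y-linked RNA (Ddx3y, 0.93) and higher immediate-early genes (median 0.46). Cd74, H2-Ab1, Cd22 and Cd3e were lower as well and Cd247 was higher, all from lists that were not called.

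**Figure D2:**
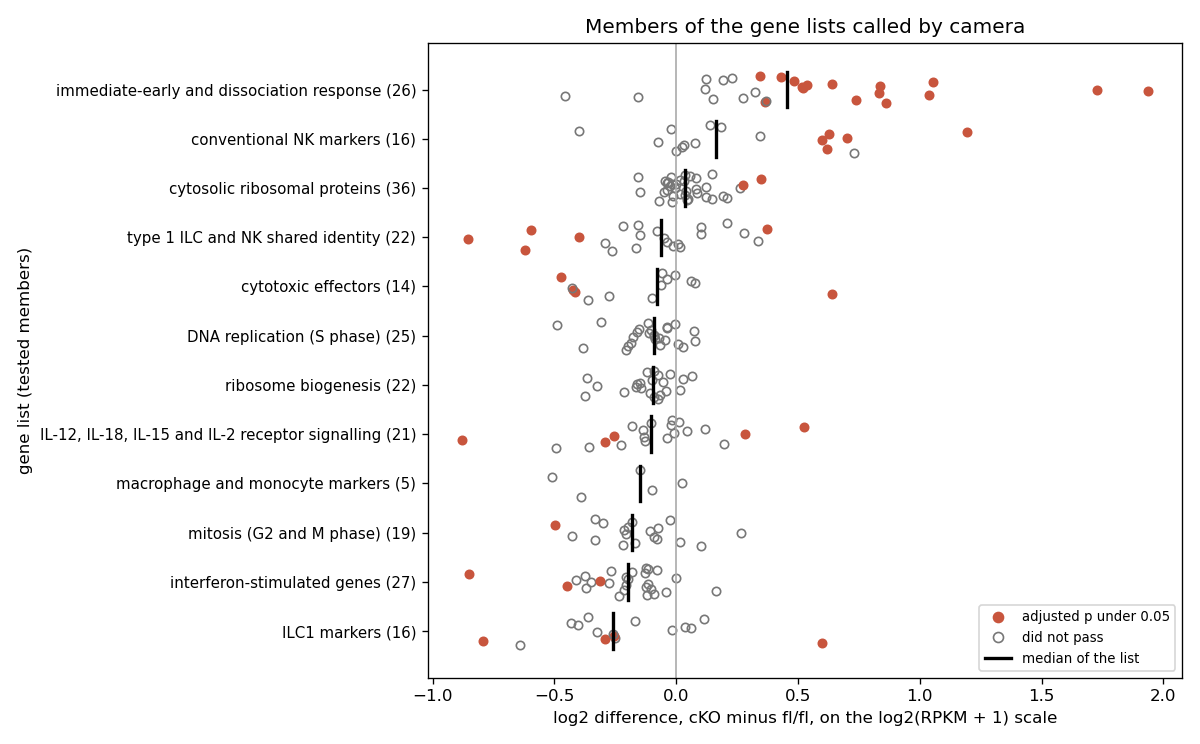
Each point is the log2 difference (cKO minus floxed, horizontal axis) of 1 tested member of the 12 gene lists called by camera (vertical axis, number of members in brackets), filled where limma's adjusted p was under 0.05, with a black bar at the list's median. The immediate-early and dissociation list has its median at 0.46 and the ILC1 markers at -0.26, while the ribosomal protein list lies close to 0 at 0.03. With an estimated correlation 2 of the lists were called, and the ILC1 and ribosomal protein lists were not (adjusted p = 0.207 and 0.543).

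Among cytotoxic effector genes, 3 passed as lower and 1, the granzyme A gene, as higher in the cKO libraries. Gzma rose from 108 ± 2.18 to 169.5 ± 2.84 RPKM (n = 3 each; adjusted p = 0.00122), whereas Gzmb fell from 66.3 ± 3.24 to 49.6 ± 3.86 RPKM (adjusted p = 0.0499) and Gzmc from 57.4 ± 3.74 to 42.5 ± 1.82 RPKM. Serpinb9, an inhibitor of granzyme B, fell from 57.1 ± 1.81 to 40.9 ± 2.09 RPKM. Of 14 cytotoxic effectors, 1 rose, 3 fell and 10 did not pass, and adjusted over the list alone 1 rose and 5 fell, with a median of -0.08. Camera gave adjusted p = 0.0357 (adjusted p = 0.207 with an estimated correlation), and 13 of 21 alternatives kept the call. The same libraries had lower Xist, higher Ddx3y and higher immediate-early genes (median 0.46). From lists not called, Cd74, H2-Ab1, Cd22 and Cd3e were lower and Cd247 was higher. Gzmb lost its call in 14 of 19 alternatives, Gzmc in 9, each library left out among them, and Serpinb9 in 6, while Gzma kept it; Gzmb and Gzmc are paralogs whose reads can be shared.

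Genes of cytokine receptors and their signalling passed in both directions. Socs3, a feedback inhibitor of cytokine signalling, rose from 70.0 ± 3.37 to 101 ± 2.70 RPKM and the kinase gene Jak1 from 177 ± 1.96 to 216 ± 2.98 RPKM (n = 3 each), beside the decreases of Il2ra and Il18r1. Of 21 genes of IL-12, IL-18, IL-15 and IL-2 receptor signalling, 2 rose, 3 fell and 16 did not pass, against 2 and 7 adjusted over the list alone. Their median was -0.10 and camera gave adjusted p = 0.0466 (adjusted p = 0.525 with an estimated correlation), kept in 9 of 21 alternatives. Among 11 effector cytokine and chemokine genes, Tnfsf14, which encodes LIGHT, fell from 37.6 ± 2.49 to 26 ± 1.73 RPKM and the lymphotoxin gene Lta from 24.6 ± 1.84 to 17.8 ± 0.469 RPKM, 0 rose and 9 did not pass. In limma 1 lay above and 3 below at an unadjusted p under 0.05, voom called 0 higher and 2 lower, and adjusted over the list alone 1 rose and 3 fell. That list was not called (median 0.09, camera adjusted p = 0.768), and fry placed it on the lower side (adjusted p = 0.584). The same cKO libraries had lower Xist, higher Ddx3y and higher immediate-early genes (median 0.46). From lists not called, Cd74, H2-Ab1, Cd22 and Cd3e were lower and Cd247 was higher. Tnfsf14 and Il18r1 lost their calls when any of the 6 libraries was left out, and Lta and Jak1 with 5 of the 6.

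Immediate-early and dissociation-response genes formed the list with the smallest camera p. Besides Fos and Hspa1b, Klf4 rose from 44.0 ± 0.201 to 92.5 ± 3.0 RPKM and Hspa1a from 10.7 ± 1.46 to 43.4 ± 1.91 RPKM (SD, n = 3 each). Nr4a1, a rapidly induced nuclear receptor gene, was at 69.9 ± 3.07 and 82.0 ± 2.35 RPKM and did not pass (adjusted p = 0.101). Of 26 tested members, 16 rose, 0 fell and 10 did not pass in limma, with 21 above and 1 below at an unadjusted p under 0.05 and 20 and 0 passing with voom. Adjusted over the list alone, 21 rose and 1 fell. Camera gave adjusted p = 4.53e-34 (adjusted p = 0.00414 with an estimated correlation), and the call held in 21 of 21 alternatives. The libraries with the higher values were also those with lower Xist (log2 difference -1.65) and higher Ddx3y (0.93). They had lower Cd74, H2-Ab1, Cd22 and Cd3e and higher Cd247, from lists that were not called. Klf6, chosen after its value was seen, rose from 65.7 ± 1.40 to 92.2 ± 1.82 RPKM, and 3 of 11 genes with the stem Klf rose (Fisher's exact test, adjusted p = 0.00928). Klf4 and Klf6 are also members of the immediate-early list, so this family count is not separate from it.

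Of the interferon-stimulated genes, 26 of 27 lay lower in the cKO libraries and 3 passed. Ifit3 fell from 108 ± 0.872 to 78.6 ± 4.27 RPKM, Mx1 from 27.4 ± 0.920 to 21.9 ± 0.376 RPKM and Rsad2, which encodes viperin, from 4.37 ± 0.567 to 1.98 ± 0.356 RPKM (n = 3 each; adjusted p = 0.0110, 0.0412 and 0.0419). Of 27 members, 0 rose, 3 fell and 24 did not pass in limma, with 1 above and 11 below at an unadjusted p under 0.05, and voom called 0 and 5. Adjusted over the list alone 1 rose and 7 fell. The median was -0.20, and camera gave adjusted p = 4.84e-07 (adjusted p = 0.0491 with an estimated correlation), a call held in 21 of 21 alternatives. Of 8 tested genes with the Schlafen stem Slfn, 3 fell (Fisher's exact test, adjusted p = 0.00515), namely Slfn1 (4.29 ± 0.323 to 2.17 ± 0.315 RPKM), Slfn2 (353 ± 3.07 to 286 ± 15.5 RPKM) and Slfn5 (12 ± 0.791 to 7.85 ± 0.499 RPKM), chosen after their values were seen. In the same libraries immediate-early genes (median 0.46) and Y-linked RNA were higher and Xist was lower. Cd74, H2-Ab1, Cd22 and Cd3e were lower too and Cd247 was higher, all from lists that were not called. The calls of Mx1, Rsad2, Slfn1, Slfn2 and Slfn5 were lost when any of the 6 libraries was left out, and that of Ifit3 in 4 of 19 alternatives.

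Among genes of cell division and ribosome assembly, 1 passed the test. Mki67, the proliferation marker, fell from 28.2 ± 0.954 to 19.7 ± 1.04 RPKM (n = 3 each; adjusted p = 0.0141), while Top2a was at 12 ± 0.394 and 11.8 ± 0.0688 RPKM. Of 19 mitosis genes, 0 rose, 1 fell and 18 did not pass, with 0 and 3 adjusted over the list alone, 0 and 3 at an unadjusted p under 0.05 and 0 and 2 with voom (median -0.18, camera adjusted p = 0.0115, adjusted p = 0.207 with an estimated correlation). Of 25 S phase genes, 0 rose and 0 fell in limma, all 25 did not pass, 0 and 0 passed adjusted over the list alone, 0 lay above and 4 below at an unadjusted p under 0.05, and voom called 0 and 0 (median -0.09, camera adjusted p = 0.0272, adjusted p = 0.207 with an estimated correlation). Of 22 ribosome biogenesis genes, 0 rose and 0 fell in limma, 22 did not pass, 0 rose and 2 fell adjusted over the list alone, 0 lay above and 8 below at an unadjusted p under 0.05, and voom called 0 and 3 (median -0.10, camera adjusted p = 0.00186, adjusted p = 0.207 with an estimated correlation). Of the cytosolic ribosomal protein genes, Rps14 rose from 224 ± 5.30 to 272 ± 8.03 RPKM and Rps27 from 239 ± 9.59 to 304 ± 18.8 RPKM, and 21 lay above 0 and 15 below. Of these 36 genes, 2 rose, 0 fell and 34 did not pass in limma, 6 lay above and 1 below at an unadjusted p under 0.05, 4 and 0 passed with voom, and 3 and 0 passed adjusted over the list alone (median 0.03, camera adjusted p = 0.0066, adjusted p = 0.543 with an estimated correlation).

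The same cKO libraries had higher immediate-early genes (median 0.46), lower Xist and higher Ddx3y. From lists not called, Cd74, H2-Ab1, Cd22 and Cd3e were lower and Cd247 was higher. The mitosis call was kept in 18 of 20 alternatives, and those of S phase, ribosome biogenesis and ribosomal proteins in 17, 20 and 17 of 21. The S phase list was at adjusted p = 0.103 with the filter at 5 RPKM and 0.0555 without floxed replicate 1, and without cKO replicate 2 the S phase and mitosis lists were at 0.0658 and 0.0546. The ribosomal protein list had a median of -0.000526 and adjusted p = 0.642 after quantile normalization, and adjusted p = 0.386 with fry and 0.338 without floxed replicate 2. Rps14 and Rps27 lost their calls when any of the 6 libraries was left out, and Mki67 without floxed replicate 2 or 3 or cKO replicate 2 or 3.

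Clock genes passed in both directions, and their list was not called by camera, which looks for a shared direction. Arntl, which encodes the activator BMAL1, fell from 5.24 ± 0.270 to 2.37 ± 0.290 RPKM (n = 3 each; adjusted p = 0.0127) and Cry1, a repressor of the clock, from 10.2 ± 0.818 to 5.18 ± 0.421 RPKM (adjusted p = 0.00985), while Nfil3 rose. Per1 was at 22.5 ± 0.459 and 26.1 ± 0.669 RPKM (adjusted p = 0.126). Of 13 clock genes, 1 rose, 2 fell and 10 did not pass, and adjusted over the list alone 4 rose and 3 fell. At an unadjusted p under 0.05, 5 lay above and 3 below, and voom called 4 and 2. Their median (-0.10) and mean (-0.06) were negative while camera pointed up (adjusted p = 0.698). Arntl lost its call in 5 of 17 alternatives and Cry1 in 2 of 19. The same libraries had lower Xist, higher Ddx3y and higher immediate-early genes (median 0.46).

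Of the memory and lymphoid-homing genes, Klf2, a zinc-finger factor gene, rose from 44.7 ± 5.47 to 74.2 ± 5.34 RPKM (n = 3 each; adjusted p = 0.0230), and Il7r fell. Tcf7, a transcription factor gene of memory lymphocytes, was at 226 ± 7.24 and 239.6 ± 3.54 RPKM (adjusted p = 0.397). Of 13 tested genes, 1 rose, 1 fell and 11 did not pass, against 2 and 2 adjusted over the list alone, and camera gave adjusted p = 0.561, pointing up with the mean (0.03) and against a median of -0.000722. Centring, quantile normalization and voom turned that median to 0.026, 0.0396 and 0.000472. Of 20 trafficking receptors and integrins, 0 rose and Cxcr6 alone fell in limma, 19 did not pass, 4 rose and 5 fell adjusted over the list alone, 6 lay above and 6 below at an unadjusted p under 0.05, and voom called 3 and 5 (median -0.02, camera adjusted p = 0.934). The median of that list was 0.00557 after centring and 0.0166 after quantile normalization, and fry gave adjusted p = 0.0255 on the lower side. Nr4a2 rose from 21.4 ± 1.53 to 30.4 ± 0.633 RPKM among 11 checkpoint genes, of which 1 rose, 0 fell and 10 did not pass in limma. There, 3 lay above and 3 below at an unadjusted p under 0.05, voom called 3 and 2, and 3 rose and 3 fell adjusted over the list alone (median -0.13, camera adjusted p = 0.967). Among 20 apoptosis regulators, the NOXA gene Pmaip1 rose from 9.35 ± 0.619 to 15.4 ± 0.604 RPKM and Bcl2a1b, which shares 49.1% of its exon bases with Gm29094, fell from 12.7 ± 0.724 to 7.87 ± 0.247 RPKM. The other 18 did not pass, 2 rose and 4 fell adjusted over the list alone, and camera gave adjusted p = 0.627 (median 0.06). With libraries left out in turn, Klf2 and Nr4a2 lost their calls in 5 of 6 fits, Bcl2a1b in 3 and Pmaip1 in 2.

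Metabolic lists were not called. In limma 0 genes rose and 0 fell among 17 of cholesterol synthesis, 18 of glycolysis, 33 of oxidative phosphorylation, 18 of fatty acid oxidation and 13 mitochondrially encoded genes, with 0 and 0 in each adjusted over the list alone and 0 and 0 with voom. At an unadjusted p under 0.05, 0 cholesterol genes, 3 glycolysis genes (lower), 3 oxidative phosphorylation genes (higher), 1 fatty acid oxidation gene (lower) and 1 mitochondrial gene (lower) were found. Camera gave adjusted p = 0.972 for cholesterol synthesis (median -0.05, mean -0.02, camera pointing up), 0.0796 for glycolysis (median -0.09), 0.516 for oxidative phosphorylation (median 0.01, mean -0.00434), 0.460 for fatty acid oxidation (median -0.05) and 0.698 for mitochondrial genes (median -0.05). Pkm, the main pyruvate kinase of lymphocytes, was at 62.0 ± 0.371 and 56.9 ± 1.66 RPKM, and glycolysis was called by fry (adjusted p = 0.0162) and without a filter (adjusted p = 0.0196). The median of oxidative phosphorylation was -0.00506 after quantile normalization. For cholesterol synthesis camera pointed down after centring and with voom.

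Among markers of antigen-presenting and B cells, 3 passed as lower in the cKO libraries. Cd74, the invariant chain of MHC class II, fell from 54.1 ± 3.93 to 32.0 ± 4.61 RPKM, H2-Ab1, an MHC class II chain, from 41.6 ± 3.06 to 26.8 ± 1.14 RPKM and the B cell receptor modulator Cd22 from 9.93 ± 0.285 to 6.49 ± 0.649 RPKM (n = 3 each). The immunoglobulin light chain Igkc was at 135 ± 12.3 and 137 ± 5.20 RPKM. Of 6 B cell markers, 0 rose, 2 fell and 4 did not pass in limma, 1 lay above and 3 below at an unadjusted p under 0.05, voom called 0 and 2, and 1 rose and 2 fell adjusted over the list alone. That list was not called (median -0.41, camera adjusted p = 0.109), but was with voom (adjusted p = 0.0284), without a filter (0.00133) and with fry (0.0316). Of 7 dendritic cell markers, 0 rose, 1 fell and 6 did not pass in limma, 2 lay above and 3 below at an unadjusted p under 0.05, voom called 1 and 2, and 2 rose and 2 fell adjusted over the list alone (median -0.07, camera adjusted p = 0.698). Of 5 macrophage and monocyte markers, 0 rose, 0 fell and 5 did not pass in limma, 0 lay above and 2 below at an unadjusted p under 0.05, voom called 0 and 1, and 0 rose and 2 fell adjusted over the list alone. Their median was -0.15 and camera gave adjusted p = 0.0466 (adjusted p = 0.207 with an estimated correlation), a call kept in 10 of 19 alternatives. Cd74 and Cd22 lost their calls with 5 of the 6 libraries left out in turn and H2-Ab1 with 3. Lyz2, a macrophage lysozyme, was at 23.4 ± 1.69 and 20.9 ± 0.913 RPKM. In the same cKO libraries Xist was lower, and Ddx3y and immediate-early genes (median 0.46) were higher.

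The marker lists of T cells and ILC3s were not called, although 3 of their genes passed. Cd3e, a T cell receptor complex chain, fell from 5.35 ± 0.430 to 2.93 ± 0.142 RPKM, and Cd247, the ζ chain used by T cell and NK receptors, rose from 26.1 ± 0.598 to 32.4 ± 0.365 RPKM, with 56.4% of its exon bases opposite Pou2f1 (n = 3 each). Of 13 T cell markers, 1 rose, 1 fell and 11 did not pass, against 2 and 3 adjusted over the list alone (median -0.00447, mean -0.11, camera pointing up with adjusted p = 0.972). Cd3e and Cd247 lost their calls when any of the 6 libraries was left out. Centring and quantile normalization turned that median to 0.0222 and 0.0139. Of 8 ILC3 markers, 0 rose, Lta fell and 7 did not pass in limma, 1 lay above and 2 below at an unadjusted p under 0.05, voom called 0 and 2, and 0 rose and 2 fell adjusted over the list alone (median 0.03, camera pointing down with adjusted p = 0.698). Too few members were tested for camera among markers of ILC2s (4), plasma cells (3), erythroid (2), liver (2), stromal cells (1) and neutrophils (0); in limma 0 of these rose and 0 fell. At an unadjusted p under 0.05, 0 lay above, and 1 ILC2, 2 plasma cell, 1 erythroid and 1 stromal marker below, and voom called 1 plasma cell marker lower. Adjusted over the list alone, 0 rose, and 1 ILC2, 2 plasma cell and 1 stromal marker fell. The ILC2 factor Gata3 was at 15.7 ± 0.724 and 17.1 ± 2.08 RPKM, and the plasma cell factor Xbp1 at 27.1 ± 1.09 and 21.9 ± 1.67 RPKM.

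Sex-linked RNA differed between the groups as well. Xist fell from 31.9 ± 3.16 to 9.43 ± 0.394 RPKM (n = 3 each; adjusted p = 0.000708), Ddx3y rose from 10.4 ± 0.498 to 20.8 ± 0.438 RPKM (adjusted p = 0.00165) and Eif2s3y from 8.33 ± 0.918 to 16.2 ± 0.695 RPKM (adjusted p = 0.00690). Both Xist and Y-linked RNA were present in each of the 6 libraries. Tsix, of which 32% of exon bases lie opposite Xist, fell from 14.3 ± 2.35 to 4.93 ± 0.199 RPKM. Without genes on X and Y, 72 genes rose, 74 fell and 9 lists were called. Of the 168 genes called with all chromosomes, 12 lie on X or Y and could not enter that fit, and 146 were called again. Leaving out X and Y genes does not remove an effect of sex on genes of other chromosomes.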

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

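The voom fit and the fits without X and Y genes, short genes or genes sharing exon bases were chosen after the results were seen. Against 83 higher and 85 lower genes, counts were 44 and 36 without a filter, 39 and 35 in limma without the trend, 13 and 10 at an absolute log2 difference of at least 1, and 226 and 307 with voom on recovered reads. They stayed within 1.5 times with both pseudocounts, the filter at 5 RPKM, both scalings, quality weights and the fits without X and Y, short or exon-sharing genes. Of the 168 genes, 151 were called again with voom, 79 without a filter and 72 without the trend. Without a filter more genes enter the adjustment, and the size limit removes genes by construction; for voom and the trend the cause was not tested. Leaving out 1 library, which leaves fewer samples, gave 33–50 higher, 27–39 lower genes and 6–10 lists. Without floxed replicate 1, 2 or 3 the counts were 50 and 39, 48 and 31, and 41 and 29, with 8, 7 and 10 lists. Without cKO replicate 1, 2 or 3 they were 40 and 34, 33 and 27, and 34 and 29, with 10, 6 and 10 lists. With the replicate number as a block, 37 and 23 genes and 8 lists were called. Same-numbered libraries did not deviate together (r = -0.03, 0.01 and 0.04 across genes, which are not independent). Of 3 floxed libraries, 1 correlated best with its own number. These values show no sign of pairing by number but cannot exclude a weak one, and the labels do not state any. Against 12 lists, 6 were called with the filter at 5 RPKM, where fewer genes were tested, and 2 with an estimated correlation; fry called 13. Rora was at -0.29 with adjusted p = 0.0242 with voom, the only alternative in which it passed, against 0.202 to 0.464 in the others. Of 60 called genes named, 20 kept their call in every refit, the limit on the size of the difference left aside, 9 lost it only with a library left out or under the block, and 0 changed direction in any. Single genes kept their side of the threshold in 922 comparisons, lost it in 280 and gained it in 1; lists did so in 498, 56 and 6. Alternatives planned for tables with whole-number counts (DESeq2 and other size factors) were not run, because the deposited table holds RPKM. The recovered reads would have allowed them, and only voom was fitted to these reads. Depth limits the microRNA genes, as Mir3058 had 0 to 2 reads in each floxed library.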

Other observations

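The tests of library scaling, of a male and female mix, of a misplaced library and of the NK cell share were chosen after the results were seen, while those of the second chaperone list, the Klra sums and the other splits were set beforehand.

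Of 26 genes of the immediate-early and dissociation response, 16 rose in the cKO libraries, and scaling of the libraries and a difference in tissue handling are candidate explanations beside the genotype. Centring each library moved the median of all tested genes by only 0.0267 and left that of the 26 members at 0.483. So small a shift argues against a scaling factor common to all genes as the cause. A second list of 15 heat-shock chaperones and co-chaperones had a median log2 difference of -0.0379, with 7 members above 0 and 1 that rose, and 0.00055 after quantile normalization. Its members went both ways, and a short stress need not reach all chaperones, so this value does not exclude handling, although the second list was not higher. The labels give no batch and no handling of single libraries, so handling and genotype cannot be told apart for these genes. The genotype remains an untested alternative.

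Lower Xist with higher Y-linked RNA may reflect a different mix of male and female cells in the groups. The log2 ratios of Ddx3y, Eif2s3y, Kdm5d and Uty spanned 0.113, against a largest SE of 0.181 for a single ratio, so they shared a ratio near 1.94, while Xist was at 0.295 of the floxed level. Solved together, and assuming equal RNA per cell in both sexes, these give a male share of 42.9% in floxed and 83.1% in cKO libraries. Of 4 X-linked genes that escape silencing, 3 lay below 0 (Kdm6a -0.43, Kdm5c -0.24, Eif2s3x -0.21) and Ddx3x at 0.10, and none passed. In 0 of the 5 sex-linked genes did the groups overlap. Xist, Ddx3y and Eif2s3y were named by a rule that asks for this, and Kdm5d and Uty shared the ratio of the Y-linked genes. The count therefore cannot decide on a single misplaced library. The sex of the animals, which the labels do not give, stays open and untested as a source of the other differences.

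The called shifts of the ILC1 and NK marker lists, which are lost with an estimated correlation, could come from a larger share of conventional NK cells, from reads moved between Klra paralogs, or from a change within the cells. The log2 differences of the 16 NK markers had an SD of 0.409, over 2 times their median SE of 0.0803, so they moved apart by more than their error and a larger NK share alone is argued against. Itga2 and, chosen after their values were seen, S1pr5 and Cx3cr1 lay near 0 (0.03, -0.02 and -0.000794) while Klra9 was at 1.19. The summed reads of the Klra genes were higher by 0.687 on the log2 scale, which argues against exchange of reads within the family as the whole cause. A sum does not show how reads were divided among the members, so exchange may still shape the values of single Klra genes. A changed NK cell subset, a smaller change in NK share and an effect of the genotype within ILC1s stay open, untested.

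Splitting the 6 libraries into 3 and 3 in all 10 ways, 1 split, the real one, gave 83 higher genes, 85 lower genes and 12 lists; the highest of the other splits were 2, 2 and 4. The 10 splits are too few for a share under 0.05.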
